A study of Homo sapiens with 12 samples.

How the data were processed

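Polyadenylated RNA of 12 libraries from HEK293 Flp-In cells was sequenced with a stranded kit, 3 libraries for each of 4 groups. The groups were a non-targeting siRNA (siNT), an siRNA against TAF5 (siTAF5), and that siRNA followed by doxycycline-induced, siRNA-resistant TAF5 in full length (FL) or without exon 8 (ΔE8). Groups were taken from the sample titles. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these samples, which is possibly technical. The labels do not state the line in which the siNT and siTAF5 cells were grown. They give different doxycycline doses for FL and ΔE8 in a notation that appears to have lost an exponent, so no dose is printed.

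The deposited table holds expected counts, that is estimated reads per gene that were not normalized, as the values show: 46.5% of entries were not whole. The submitters' processing notes name cutadapt 1.18, STAR 2.7.0f, Partek 10.0.23.0531, DESeq2 without a version and the genome build hg38, and state neither their roles nor their order. The quantifier, its annotation release and its strand setting are not given in the sources used here. The table had 32010 Ensembl genes, of which 8010 had no name and 302 had 0 counts in every library. Of these IDs, 30464 (95.2%) were found in GENCODE release 29, 99.9% of them on the same chromosome. Start positions were equal for 69.9%, and the stop position minus 1 equalled the annotated end for 70%, so positions are printed with 1 base taken from the stop. Symbols were taken from the names in the table and matched to list genes by current or former symbol, with 705 of 706 list genes found.

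The design was written for counts, and the table turned out to hold estimated counts. These were rounded to whole numbers, which changed no library total by more than 91.27 counts, and used in the planned count model. Library totals ran from 41.8 to 62.5 M, as given per library with the results. Intervals for counting error were not given, since reads without molecular identifiers are not independent molecules and the spread between libraries was larger than counting error: replicate pairs had a chi-square per degree of freedom between 2.61 and 5.16. The common biological coefficient of variation was 2.82% and the prior degrees of freedom 11.3.

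Choices of samples, tests, gene lists, named genes and alternatives were made before the data were examined, except where stated. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with a minimum count of 10, which left 19424. Libraries were scaled by trimmed mean of M values, and the 12 libraries were fitted in 1 edgeR quasi-likelihood model with a mean for each group and no replicate block. The 6 comparisons were tested two-sided, with Benjamini-Hochberg adjustment over the 19424 genes in each and a threshold of 0.05 without a minimum fold. The SE of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, counts scaled to a common library size, as mean and SD over 3 libraries. No spike-in was used, so changes are relative to the bulk of genes, and a change in total RNA per cell is not visible.

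Gene lists were tested with limma camera on voom values with a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison, and again with an estimated correlation. The lists were TFIID subunits other than TAF5, SAGA subunits, RNA polymerase II and general factors, Mediator subunits, p53 targets, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, ribosome biogenesis, cytosolic ribosomal proteins, ATF4 and the integrated stress response, unfolded protein response, heat shock, cholesterol, interferon-stimulated, immediate early, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, glycolysis and hypoxia, splicing factors, lysosome and autophagy, extracellular matrix and TGF-beta, neuronal, apoptosis, markers of fibroblasts, of keratin-rich epithelial cells and of blood cells, and nuclear-retained noncoding RNAs. They were written from general knowledge, not from these samples. Counts called within a list are given over all genes tested and adjusted over the list alone.

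Named genes followed a rule. TAF5 came first. In siTAF5 against siNT and in ΔE8 against FL, the 8 genes higher and the 8 lower with the largest log2 change were named among those past the threshold, with an average log2 CPM of at least 2 and no overlap between the libraries of the groups. In the other 4 comparisons the first 4 each way were named. For each list called by camera, the 4 members with the smallest adjusted p could be named, and any TFIID member in any comparison.

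Genes called in siTAF5 against siNT were tested as lists in ΔE8 against FL, which shares no library with it. The share of the siTAF5 response left was cross-fitted: genes were called from 2 replicate numbers, and in the third the signed log2 differences from siNT were summed in the rescued library and divided by the same sum in the siTAF5 library. Fold changes that share a control were compared with 20 simulations of unchanged groups. Histone CPM were also summed over 59 genes, and over 21 RNAs without a poly(A) tail.

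The model was tested on simulated data with 19118 genes passing the filter. In simulated ΔE8 against FL, 78% of 50 genes changed by 0.25 on the log2 scale were called, 94% at 0.5, 100% at 1 and 100% at 2, with 15 false calls. ΔE8 against siTAF5 gave 74%, 96%, 100% and 100% with 14 false calls, and ΔE8 against siNT 78%, 94%, 100% and 100% with 13. Where nothing was changed, siTAF5 against siNT gave 1 false call, FL against siTAF5 1 and FL against siNT 0. In limma, camera gave a p-value of 6.74e-75 for 60 genes shifted by 0.2 on the log2 scale, and of 0.609 for 60 genes that were not shifted. The cross-fitted share came to 30% where 30% was simulated and to 69.5% where 70% was.

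Alternatives were the DESeq2 Wald test, relative log expression and upper-quartile factors, library totals only, no filter and a filter of 1 CPM in 3 libraries, a replicate block, only the 6 libraries compared, leaving out each library in turn, a minimum of 2-fold, and for lists an estimated correlation, fry, a block and library totals. Chosen after seeing the data were leaving out the 3 libraries under 45 M counts, thinning to the smallest library, leaving out each library for the lists, the families and the RNAs without a tail, and response lists without histone and ribosomal protein genes. Every split of the 6 libraries of a comparison into groups of 3 was also fitted, 10 in each. Isoforms, exons and splicing were not analysed here, since the table holds 1 value per gene.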

Results

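Polyadenylated RNA was sequenced from HEK293 Flp-In cells, a human embryonic kidney line with a fixed genomic site that accepts a transgene. TAF5 encodes a subunit of TFIID, the complex that binds core promoters for RNA polymerase II. The 12 libraries formed 4 groups of 3. The siNT group received a non-targeting siRNA and the siTAF5 group an siRNA against TAF5. The FL group received the TAF5 siRNA and then expressed an siRNA-resistant full-length TAF5. The ΔE8 group did the same with TAF5 lacking exon 8. Doxycycline was added 24 h after transfection and left for 48 h. The question was whether exon 8 of TAF5 matters for gene expression. Library totals were 54.8, 60.7 and 61.8 M estimated counts for siNT replicates 1 to 3, 46.4, 55.7 and 55.9 M for siTAF5, 62.5, 42.6 and 43.8 M for FL, and 61.2, 55.9 and 41.8 M for ΔE8. Principal component 1 held 34.5% and component 2 held 19% of the variance, and the 4 groups did not overlap in that plane. Mitochondrially encoded genes took 0.87% to 1.29% of the counts of a library and cytosolic ribosomal protein genes 6.75% to 8.48%.

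TAF5 (chromosome 10, 103367966 to 103389065, hg38) was measured first in every library. Normalised levels were 39.17, 40.5 and 40.21 CPM (counts scaled to a common library size) in the siNT libraries, 6.131, 7.354 and 6.685 in siTAF5, 102.6, 105.6 and 107.4 in FL, and 87.61, 87.49 and 88.86 in ΔE8. Group levels were 40.0 ± 0.698 CPM (mean ± SD, n = 3 here and below) in siNT and 6.72 ± 0.612 in siTAF5, which kept 16.8% of the siNT level. They were 105 ± 2.44 CPM in FL, 2.63-fold the siNT level, and 88 ± 0.757 CPM in ΔE8, 2.20-fold the siNT level. TAF5 RNA therefore stood above the endogenous level in both rescued groups. TAF5 counts were 1.2-fold lower in ΔE8 than in FL (log2 difference -0.26, SE 0.031, edgeR adjusted p = 2.12e-06). Exon 8 of an annotated TAF5 transcript with 11 exons spans 103385326 to 103385490, 165 bases that are all coding and keep the reading frame. Counts were not corrected for transcript length, so the missing 165 bases lower the ΔE8 counts by themselves, by an amount not estimated here. Counts per gene do not resolve that exon. They check the knockdown and the presence of a transgene, and do not check which of the FL and ΔE8 labels is which.

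**Figure D1:**
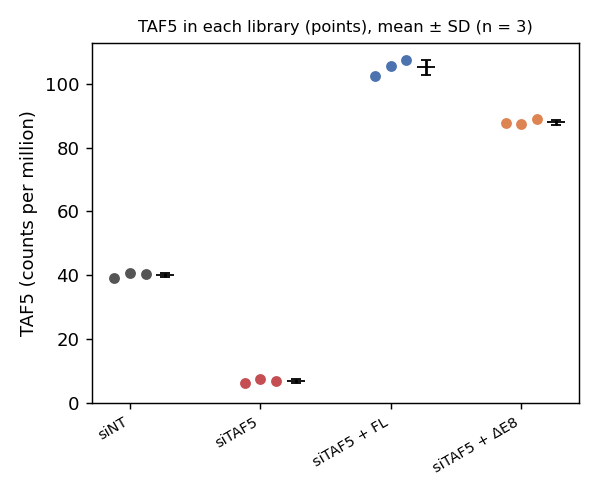
TAF5 level in CPM (y axis) for each of the 12 libraries (points) in the 4 groups (x axis), with the mean and SD of each group (n = 3). The siTAF5 libraries averaged 6.72 CPM against 40.0 in siNT, 105 in FL and 88.0 in ΔE8.

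Depletion of TAF5, siTAF5 against siNT, asked which transcripts depend on TAF5. RNA of POLR2A, the largest RNA polymerase II subunit (chromosome 17, 7484366 to 7514616), rose 2.06-fold to 707 ± 11.6 CPM from 342 ± 5.13 (SE of log2 0.024, edgeR adjusted p = 5.61e-17). The TFIID subunit TAF12 (chromosome 1, 28587829 to 28648291) rose 1.89-fold to 32.2 ± 0.733 CPM (edgeR adjusted p = 1.57e-12), and the histone gene H2BC12 rose 2.17-fold to 139 ± 3.48 CPM (edgeR adjusted p = 1.27e-14). SNHG3, a host of small nucleolar RNAs (chromosome 1, 28505980 to 28510892), fell 3.25-fold to 20.1 ± 1.43 CPM from 65.5 ± 0.221 (edgeR adjusted p = 6.73e-16), and ribosomal protein transcript RPS25 fell 1.63-fold to 279.6 ± 2.83 CPM. The test called 4802 genes higher and 4848 lower among 19424, which is 49.7%, at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). With scaling by library totals only, the split was 5662 and 4140, and with upper-quartile factors 4459 and 5254. Most calls were small: the median size of log2 change among them was 0.271, and 323 higher and 197 lower genes changed at least 2-fold. The libraries of the groups did not overlap for 57.3% of genes, against 10% by chance for 3 against 3.

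The 8 genes with the largest rise were ZNF425, a zinc finger gene (3.39-fold, 3.24 ± 0.215 to 11 ± 0.671 CPM), TLCD1 (2.89-fold), DHRS2 (2.84-fold), PSMG3-AS1 (2.82-fold), the histone gene H4C8 (2.73-fold), NEAT1 (2.72-fold), TP53I3 (2.68-fold) and WDR31 (2.45-fold). NEAT1, the noncoding RNA of nuclear paraspeckles (chromosome 11, 65422774 to 65445540), reached 135 ± 6.57 CPM from 49.5 ± 4.45 (edgeR adjusted p = 1.19e-12). PSMG3-AS1 is antisense to PSMG3, and its level is uncertain because the strand setting of the counting is not given in the sources used here. After TAF5 and SNHG3, the largest falls were in RAPGEF3, an exchange factor for small GTPases (2.77-fold, 8.74 ± 0.267 to 3.16 ± 0.145 CPM), CALML4 (2.48-fold), the interferon-inducible BST2 (2.43-fold), PCDH19, a protocadherin on chromosome X (2.39-fold, 29.1 ± 0.689 to 12.2 ± 0.683 CPM), the hormone subunit CGA (2.32-fold) and the vesicle GTPase RAB3A (2.28-fold). Adjusted p of these 16 genes lay between 2.09e-18 (TAF5) and 3.18e-08 (CGA) by edgeR, and each had no overlap between the groups.

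Histone and p53 target transcripts moved up as groups. Of 18 measured replication-dependent histone genes, 13 rose and 0 fell (13 higher and 0 lower adjusted over the list alone), with a median log2 change of 0.88 (limma camera adjusted p = 1.65e-07, and adjusted p = 0.0111 with an estimated correlation). H1-2 (2.17-fold, to 55.8 ± 0.683 CPM), H3C10 (2.08-fold) and H2AC6 (2.08-fold) had the smallest adjusted p beside H2BC12. Of 25 p53 target genes, 18 rose and 2 fell (18 higher and 3 lower adjusted over the list alone), median 0.30 (camera adjusted p = 1.28e-06, and adjusted p = 0.0111 with an estimated correlation). TP53INP1 rose 1.98-fold, the polymerase gene POLH 1.61-fold, the repair gene XPC 1.49-fold, and the cell cycle inhibitor CDKN1A 1.46-fold, from 92.9 ± 3.1 to 136 ± 3.25 CPM. Of the 9 lists called with the preset correlation, these 2 were also called with an estimated one.

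Transcription machinery lists were called higher with the preset correlation. Of 15 TFIID subunits other than TAF5, 8 rose and 1 fell (8 higher and 2 lower adjusted over the list alone), median 0.085 (camera adjusted p = 0.00965, and adjusted p = 0.116 with an estimated correlation). TAF9B (1.29-fold), TAF13 (1.24-fold), TAF3 (1.24-fold), TAF11 (1.23-fold), TAF4 (1.21-fold) and TAF6 (1.14-fold) rose, TAF8 fell 1.3-fold, and TBP did not pass (log2 0.023, edgeR adjusted p = 0.651). TAF2 passed narrowly (log2 0.085, edgeR adjusted p = 0.0459), but not under 12 of the alternative settings, where its adjusted p lay between 0.051 and 0.322. In the list of RNA polymerase II and general factors 13 of 29 rose and 3 fell (14 higher and 3 lower adjusted over the list alone), median 0.085 (camera adjusted p = 0.00820, and adjusted p = 0.255 with an estimated correlation), with GTF2A1 1.48-fold, POLR2L 1.43-fold and POLR2D 1.14-fold higher. Mediator subunits had 15 of 32 higher and 4 lower (15 higher and 4 lower adjusted over the list alone), median 0.085 (camera adjusted p = 0.0124, and adjusted p = 0.205 with an estimated correlation), led by MED29 (1.59-fold), MED20 (1.57-fold), CDK19 (1.4-fold) and MED12 (1.25-fold). Without siNT replicate 1 the TFIID median was 0.14, and without siTAF5 replicate 3 that of the polymerase and general factor list was 0.048, both still called.

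Ribosomal protein and amino acid response transcripts fell. Of 76 cytosolic ribosomal protein genes, 68 fell and 2 rose (3 higher and 68 lower adjusted over the list alone), median -0.25 (camera adjusted p = 1.74e-25, but adjusted p = 0.205 with an estimated correlation). RPSA fell 1.55-fold from 1219 ± 24.2 to 786 ± 9.38 CPM, RPS23 1.48-fold and RPL10 1.45-fold. Of 29 genes of the ATF4 and integrated stress response, 22 fell and 3 rose (3 higher and 23 lower adjusted over the list alone), median -0.29 (camera adjusted p = 1.95e-08, but adjusted p = 0.255 with an estimated correlation). ATF4 itself fell 1.48-fold from 671 ± 12.3 to 454 ± 11.7 CPM, asparagine synthetase ASNS 1.73-fold, the cystine transporter SLC7A11 1.83-fold and the serine synthesis gene PSAT1 1.36-fold. Of 13 mitochondrially encoded genes, 10 fell and 0 rose (0 higher and 10 lower adjusted over the list alone), median -0.18 (camera adjusted p = 0.00965, but adjusted p = 0.637 with an estimated correlation, and 0.0687 with fry). This call hung on siNT replicate 3: without it the median was -0.092 and the list was not called (camera adjusted p = 0.0731). MT-ND5, MT-ND6, MT-ND4 and MT-ATP6 fell 1.28-, 1.28-, 1.2- and 1.17-fold, and the libraries of the groups overlapped for MT-ATP6. Of 8 keratin-rich epithelial markers, 7 fell and 0 rose (0 higher and 7 lower adjusted over the list alone), median -0.29 (camera adjusted p = 0.00436, but adjusted p = 0.255 with an estimated correlation). They included CDH1 (1.82-fold), EPCAM (1.3-fold), KRT8 (1.14-fold) and CLDN4 (1.78-fold). Ribosomal protein genes can share reads with their pseudogenes, so single members are uncertain.

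The remaining 19 lists were not called by camera in siTAF5 against siNT. Counts are given as higher and lower genes. Cell cycle lists were split, with 9 higher and 12 lower of 30 G1/S and DNA replication genes (9 higher and 13 lower adjusted over the list alone, median -0.014, mean 0.0030, limma camera adjusted p = 0.828). G2/M and mitosis genes gave 7 and 15 of 27 (7 higher and 15 lower adjusted over the list alone, median -0.081, limma camera adjusted p = 0.121). Ribosome biogenesis genes gave 10 and 11 of 29 (10 higher and 12 lower adjusted over the list alone, median -0.019, limma camera adjusted p = 0.826). Splicing factors gave 10 and 8 of 32 (10 higher and 8 lower adjusted over the list alone, median -0.020, mean 0.0017, limma camera adjusted p = 0.829). SAGA subunits gave 3 higher and 3 lower of 16 (3 higher and 3 lower adjusted over the list alone, median -0.030, limma camera adjusted p = 0.940). Unfolded protein response genes gave 10 and 3 of 18 (10 higher and 3 lower adjusted over the list alone, median 0.10, limma camera adjusted p = 0.0587). Heat shock genes gave 5 and 5 of 16 (5 higher and 5 lower adjusted over the list alone, median -0.011, mean 0.054, limma camera adjusted p = 0.996). Cholesterol genes gave 7 higher and 6 lower of 24 (7 higher and 6 lower adjusted over the list alone, median -0.013, mean 0.025, limma camera adjusted p = 0.996). Interferon-stimulated genes gave 5 and 9 of 21 (5 higher and 9 lower adjusted over the list alone, median -0.17, limma camera adjusted p = 0.436). Immediate early genes gave 9 and 6 of 27 (9 higher and 6 lower adjusted over the list alone, median -0.038, mean 0.019, limma camera adjusted p = 0.828). The unfolded protein response list was called without siNT replicate 2 (camera adjusted p = 0.0404) or siTAF5 replicate 2 (0.0457).

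Among metabolic lists, nuclear-encoded oxidative phosphorylation genes gave 23 higher and 11 lower of 48 (23 higher and 11 lower adjusted over the list alone, median 0.055, limma camera adjusted p = 0.109). Glycolysis and hypoxia genes gave 5 and 15 of 29 (5 higher and 15 lower adjusted over the list alone, median -0.11, limma camera adjusted p = 0.138). Lysosome and autophagy genes gave 11 and 8 of 24 (11 higher and 8 lower adjusted over the list alone, median 0.051, limma camera adjusted p = 0.0695). Extracellular matrix and TGF-beta genes gave 3 higher and 10 lower of 24 (4 higher and 10 lower adjusted over the list alone, median -0.076, limma camera adjusted p = 0.257). Neuronal genes gave 5 and 10 of 22 (5 higher and 10 lower adjusted over the list alone, median -0.11, limma camera adjusted p = 0.230). Apoptosis regulators gave 6 and 10 of 27 (7 higher and 10 lower adjusted over the list alone, median -0.037, limma camera adjusted p = 0.478). Fibroblast markers gave 0 higher and 2 lower of 3 (0 higher and 2 lower adjusted over the list alone, median -0.42, limma camera adjusted p = 0.231). Blood cell markers gave 0 and 1 of 4 (0 higher and 1 lower adjusted over the list alone, median -0.35, limma camera adjusted p = 0.436). Nuclear-retained noncoding RNAs gave 2 and 2 of 7 (2 higher and 2 lower adjusted over the list alone, median 0.044, limma camera adjusted p = 0.456). The lysosome list was called without siNT replicate 2 (camera adjusted p = 0.0435). Median and mean, or median and test, differed in sign for the G1/S, splicing, heat shock, cholesterol and immediate early lists. A single TAF5 siRNA was used, so its effects on other transcripts are part of this comparison.

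**Figure D2:**
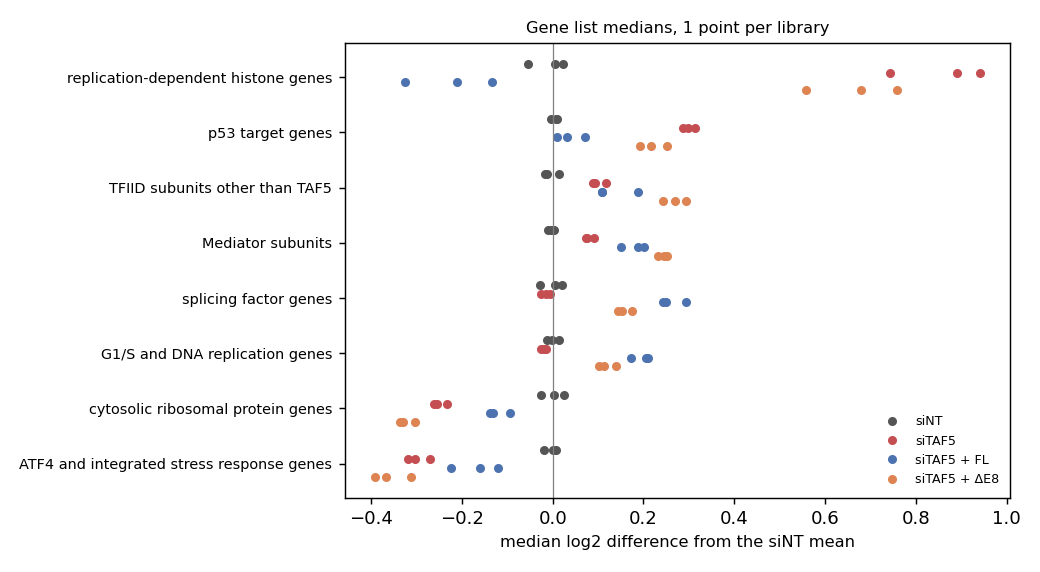
Median log2 difference from the siNT mean (x axis) over the genes of 8 of the gene lists (y axis), with 1 point per library and 1 colour per group. Histone genes lay above siNT in the siTAF5 and ΔE8 libraries and below it in the FL libraries, while ribosomal protein genes lay below siNT in all 3 groups given the TAF5 siRNA.

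Rescue with full-length TAF5, FL against siTAF5, asked what changed when the intact protein was added back. Besides TAF5 (15.6-fold), the largest rises were in the axonemal dynein DNAH17 (6.13-fold, 3.89 ± 0.339 to 24.1 ± 2.94 CPM), the small heat shock protein HSPB8 (3.67-fold, edgeR adjusted p = 2.89e-11) and CGA (3.41-fold), which had fallen in siTAF5. DNAH17 and HSPB8 ended above siNT in FL, by 2.08 and 1.6 on the log2 scale. The largest falls were in histone genes: H2AC18 (6.77-fold, 45.2 ± 1.44 to 6.7 ± 1.1 CPM), H1-2 (4.6-fold, 55.8 ± 0.683 to 12 ± 0.919 CPM), H2AC19 (4.54-fold) and H4C15 (4.1-fold, edgeR adjusted p = 1.19e-14). H2AC18 and H2AC19, and H4C14 and H4C15, are near-identical pairs, so the split of reads within each pair is uncertain. The test called 4745 genes higher and 4732 lower (48.8% of 19424; edgeR quasi-likelihood, Benjamini-Hochberg), with 209 and 328 at least 2-fold and a median size of 0.27 on the log2 scale. With scaling by library totals only, the split was 3748 higher and 5788 lower, and with upper-quartile factors 4392 and 5095. Libraries did not overlap for 56.3% of genes, against 10% by chance.

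Replication-dependent histone genes fell as a group, with 12 of 18 lower and 1 higher (1 higher and 12 lower adjusted over the list alone), median -1.23 (camera adjusted p = 1.72e-08, and adjusted p = 0.0139 with an estimated correlation). H2BC12 fell 2.87-fold and H2BC21 3.02-fold. Of 25 p53 targets, 15 fell and 6 rose (6 higher and 16 lower adjusted over the list alone), median -0.26 (camera adjusted p = 0.000378, and adjusted p = 0.0261 with an estimated correlation). CDKN1A fell 1.46-fold to 93 ± 2.21 CPM, close to its siNT level of 92.9 ± 3.1, and TP53INP1, TNFRSF10B and FDXR fell 1.68-, 1.27- and 1.53-fold. Ribosome biogenesis genes rose (24 of 29 higher and 1 lower, 24 higher and 2 lower adjusted over the list alone), median 0.20 (camera adjusted p = 2.99e-09, and adjusted p = 0.0247 with an estimated correlation), including RRS1 (1.44-fold), RRP12 (1.41-fold), NOP14 (1.3-fold) and PPAN (1.24-fold), whose gene overlaps a neighbour. Of 32 splicing factor genes, 28 rose and 2 fell (28 higher and 2 lower adjusted over the list alone), median 0.29 (camera adjusted p = 8.69e-14, and adjusted p = 0.0411 with an estimated correlation), led by HNRNPM (1.5-fold, 391 ± 6.06 to 588 ± 15.9 CPM), SF3A1 (1.32-fold), HNRNPD (1.37-fold) and HNRNPA1 (1.36-fold). The ribosome biogenesis and splicing lists had not been called in siTAF5 against siNT (medians -0.0187 and -0.0203). In FL they stood above siNT (medians 0.167 and 0.266), so their rise was not a return to the siNT level.

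Another 9 lists were called in FL against siTAF5 with the preset correlation only. Of these, only the ribosomal protein and ATF4 lists had been called in siTAF5 against siNT, both lower. G1/S and DNA replication genes had 24 of 30 higher and 1 lower (24 higher and 1 lower adjusted over the list alone), with POLA1 1.49-fold, MCM10 1.37-fold, UHRF1 1.31-fold and MCM7 1.28-fold higher (camera adjusted p = 2.52e-09, but adjusted p = 0.0869 with an estimated correlation). G2/M genes had 20 of 27 higher and 3 lower (20 higher and 3 lower adjusted over the list alone), with TTK 1.38-fold and CCNB1 1.26-fold higher (camera adjusted p = 1.36e-06, but adjusted p = 0.136 with an estimated correlation). Ribosomal protein genes had 49 of 76 higher and 7 lower (49 higher and 8 lower adjusted over the list alone), with RPSA 1.43-fold higher at 1122 ± 16.6 CPM (camera adjusted p = 1.45e-09, but adjusted p = 0.385 with an estimated correlation). ATF4 pathway genes had 18 of 29 higher and 4 lower (18 higher and 4 lower adjusted over the list alone), with ATF4 1.47-fold and SLC7A11 2.04-fold higher (camera adjusted p = 6.70e-05, but adjusted p = 0.385 with an estimated correlation). Heat shock genes had 14 of 16 higher and 2 lower (14 higher and 2 lower adjusted over the list alone; camera adjusted p = 2.41e-06, but adjusted p = 0.104 with an estimated correlation), with HSPH1 1.47-fold higher and HSPA1B, which has a near-identical copy, 1.45-fold lower. Unfolded protein response genes had 10 of 18 higher and 2 lower (12 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0144, but adjusted p = 0.388 with an estimated correlation). Extracellular matrix genes had 15 of 24 lower and 5 higher (6 higher and 16 lower adjusted over the list alone), with FN1 1.62-fold and LOXL2 1.7-fold lower (camera adjusted p = 0.000189, but adjusted p = 0.104 with an estimated correlation). SAGA subunits had 8 of 16 higher and 0 lower (8 higher and 0 lower adjusted over the list alone), including TAF5L 1.19-fold (camera adjusted p = 0.0381, but adjusted p = 0.104 with an estimated correlation, and 0.118 with library totals). Apoptosis regulators had 16 of 27 higher and 4 lower (16 higher and 4 lower adjusted over the list alone), with BMF 1.82-fold and BBC3 1.6-fold lower and PMAIP1 1.41-fold higher (camera adjusted p = 0.0475, but adjusted p = 0.104 with an estimated correlation, and 0.0887 with library totals). Their call was also lost without siTAF5 replicate 1 (camera adjusted p = 0.0590), siTAF5 replicate 2 (0.0522) or FL replicate 3 (0.0637), and that of SAGA without FL replicate 2 (0.0602).

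Rescue with the isoform lacking exon 8, ΔE8 against siTAF5, asked what changed when that isoform was added. As in FL, the largest rises beside TAF5 (13-fold) were in DNAH17 (4.9-fold, to 19.2 ± 1.06 CPM), HSPB8 (3.2-fold, edgeR adjusted p = 1.12e-09) and CGA (2.49-fold). The largest falls were in the collagen gene COL21A1 (2.61-fold, 11.6 ± 0.781 to 4.38 ± 0.634 CPM, edgeR adjusted p = 4.23e-10), BST2 (2.48-fold), the BMP antagonist NOG (2.35-fold) and TENM1 (2.32-fold). POLR2A rose a further 1.31-fold to 926 ± 24.9 CPM, and H1-2 fell 1.44-fold to 38.6 ± 0.864 CPM, still above its siNT level of 25.6 ± 0.607. The test called 3891 genes higher and 3993 lower (40.6%; edgeR quasi-likelihood, Benjamini-Hochberg), with 120 and 178 at least 2-fold and a median size of 0.216. Scaling by library totals only gave 3321 and 4546, and upper-quartile factors 3201 and 4687. Relative log expression factors gave 4018 and 3892, the DESeq2 Wald test 3670 and 3364, and the 6 libraries alone 4137 and 3870, so the larger side depends on the processing. Libraries did not overlap for 49.9% of genes, against 10% by chance.

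Of 28 lists, limma camera called 15 in ΔE8 against siTAF5 with the preset correlation and 0 with an estimated one, where 10 had an unadjusted p under 0.05, while fry called 19. Ribosome biogenesis genes had 22 of 29 higher and 2 lower (23 higher and 2 lower adjusted over the list alone), with NOP2 1.25-fold and NOP58 1.24-fold higher (camera adjusted p = 1.76e-07, but adjusted p = 0.0930 with an estimated correlation). Splicing factor genes had 24 of 32 higher and 0 lower (25 higher and 0 lower adjusted over the list alone), with HNRNPM 1.33-fold and SRSF6 1.31-fold higher (camera adjusted p = 7.94e-10, but adjusted p = 0.0998 with an estimated correlation). G1/S genes had 20 of 30 higher and 1 lower (20 higher and 1 lower adjusted over the list alone), with CDC6 1.31-fold and CLSPN 1.27-fold higher (camera adjusted p = 1.14e-08, but adjusted p = 0.0998 with an estimated correlation). Heat shock genes had 11 of 16 higher and 0 lower (11 higher and 0 lower adjusted over the list alone), with DNAJA1 1.36-fold and HSP90AA1 1.24-fold higher (camera adjusted p = 2.90e-06, but adjusted p = 0.118 with an estimated correlation). The ribosome biogenesis, splicing, G1/S and heat shock lists had not been called in siTAF5 against siNT. Ribosomal protein genes went the other way from FL, with 43 of 76 lower and 1 higher (1 higher and 45 lower adjusted over the list alone), median -0.076, and RPL13A 1.17-fold lower (camera adjusted p = 3.67e-07, but adjusted p = 0.421 with an estimated correlation). Histone genes had 9 of 18 lower and 1 higher (2 higher and 9 lower adjusted over the list alone), median -0.21 (camera adjusted p = 0.0128, but adjusted p = 0.118 with an estimated correlation). The p53 targets had 12 of 25 lower and 5 higher (5 higher and 12 lower adjusted over the list alone), with BTG2 1.31-fold and GDF15 1.53-fold lower (camera adjusted p = 0.0295, but adjusted p = 0.118 with an estimated correlation). The other 8 called lists were the G2/M (CDC20 1.26-fold higher), TFIID (TAF3 1.25-fold higher), polymerase and general factor, Mediator (MED27 1.27-fold higher), unfolded protein response (DNAJB11 1.24-fold higher), oxidative phosphorylation (NDUFA9 1.19-fold higher), mitochondrially encoded (MT-CO1 1.2-fold lower) and extracellular matrix (ID3 1.71-fold higher, COL6A1 1.46-fold lower) lists. Their adjusted p with an estimated correlation lay between 0.0941 (Mediator) and 0.632 (mitochondrially encoded). Mitochondrially encoded genes lost their call without siTAF5 replicate 1 (median -0.091, camera adjusted p = 0.0764) or ΔE8 replicate 1 (-0.10, camera adjusted p = 0.0992), against a median of -0.15. The ribosomal protein median was -0.049 without ΔE8 replicate 2, still called.

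Both rescues were measured against the same siTAF5 libraries, so a resemblance between them is partly built in. Called in both, 2693 genes were higher and 2470 lower, where independent lists would share 951 and 973. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.614, against 0.488 in simulations of unchanged groups with the same control, and a covariance of 0.0804 against 0.0172 simulated. The 3 siTAF5 libraries are too few to give each comparison 2 of its own, so part of the excess in counts and correlation may come from the shared controls, while the simulated covariance holds that part.

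The direct comparison of isoforms, ΔE8 against FL, asked what differs when exon 8 is missing. Histone transcripts stood out: the 8 largest differences upward were H2AC18 (3.78-fold, 6.7 ± 1.1 to 25.4 ± 1.84 CPM), H1-2 (3.18-fold, 12 ± 0.919 to 38.6 ± 0.864 CPM), H2BC11 (2.88-fold), H4C15 (2.7-fold), H2AC19 (2.67-fold), H4C14 (2.53-fold), H2BC12 (2.47-fold, 48.3 ± 2.92 to 119 ± 0.977 CPM) and the histone pseudogene H2BC19P (2.39-fold). H1-2 (chromosome 6, 26055740 to 26056470) encodes a linker histone, and its difference had SE 0.046 on the log2 scale (edgeR adjusted p = 2.84e-15). Lower in ΔE8 were PCDH19 (2.67-fold, 21.4 ± 0.587 to 7.99 ± 0.982 CPM; chromosome X, 100291644 to 100410273), BST2 (2.24-fold), the glycerate kinase gene GLYCTK (2.17-fold), SNHG3 (2.13-fold, 40.3 ± 0.340 to 19 ± 1.24 CPM), ANXA1 (2.1-fold), CRTAP (1.88-fold, 173 ± 6.38 to 91.8 ± 2.85 CPM), IKZF3 (1.88-fold) and RAB3A (1.86-fold). Adjusted p of these 16 genes lay between 2.84e-15 (H1-2) and 8.96e-07 (BST2) by edgeR. The test called 3359 genes higher and 3819 lower in ΔE8 (37.0% of 19424; edgeR quasi-likelihood, Benjamini-Hochberg), with 137 and 93 at least 2-fold and a median size of 0.22. With library totals only, 4072 were higher and 3184 lower, so the larger side depends on the scaling. Libraries did not overlap for 45.7% of genes, against 10% by chance.

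Of 18 listed histone genes, 13 were higher and 0 lower in ΔE8 (13 higher and 0 lower adjusted over the list alone), median 0.94. Of the 11 lists called in this comparison, only this 1 was also called with an estimated correlation (camera adjusted p = 4.86e-12, and adjusted p = 0.00291 with an estimated correlation). H2AC6 was 2.32-fold higher. Summed over 59 replication-dependent histone genes, which avoids the split between near-identical copies, the level was 312 ± 7.09 CPM in siNT, 578 ± 3.81 in siTAF5, 181 ± 4.38 in FL and 433 ± 6.52 in ΔE8 (n = 3). Ribosomal protein genes had 66 of 76 lower and 3 higher (3 higher and 66 lower adjusted over the list alone), median -0.20 (camera adjusted p = 4.47e-27, but adjusted p = 0.182 with an estimated correlation). RPS25 was 1.44-fold, RPSA 1.39-fold, RPS23 1.37-fold and RPL10 1.36-fold lower. ATF4 pathway genes had 21 of 29 lower and 2 higher (3 higher and 22 lower adjusted over the list alone), with ATF4 at 493 ± 5.85 CPM against 666 ± 27.8 and SLC7A11 1.81-fold, SLC7A5 1.41-fold and PSAT1 1.4-fold lower (camera adjusted p = 7.37e-08, but adjusted p = 0.235 with an estimated correlation). Splicing factor genes had 22 of 32 lower and 3 higher (3 higher and 22 lower adjusted over the list alone), with HNRNPA1 1.4-fold and HNRNPD 1.25-fold lower (camera adjusted p = 7.37e-08, but adjusted p = 0.182 with an estimated correlation).

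**Figure D3:**
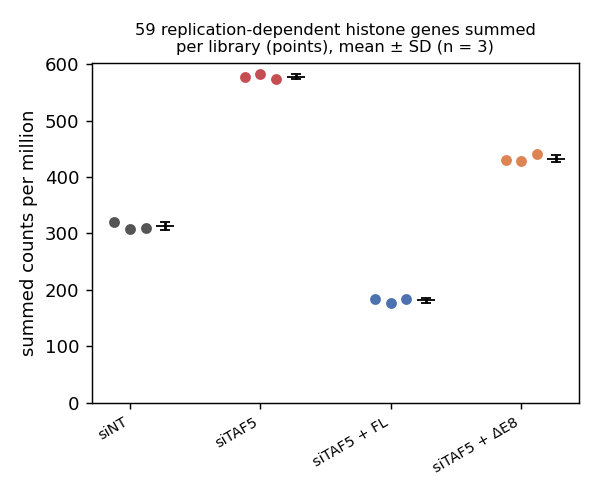
CPM summed over 59 replication-dependent histone genes (y axis) for each library (points) in the 4 groups (x axis), with the mean and SD of each group (n = 3). The sums averaged 312 in siNT, 578 in siTAF5, 181 in FL and 433 in ΔE8.

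TFIID subunits were mostly higher in ΔE8 than in FL, with 8 of 15 higher and 1 lower (8 higher and 1 lower adjusted over the list alone), median 0.12 (camera adjusted p = 0.00418, but adjusted p = 0.0704 with an estimated correlation). TAF12 was 1.63-fold higher (21 ± 0.847 to 34.1 ± 1.34 CPM, edgeR adjusted p = 1.74e-10), TAF4 1.26-fold and TAF6 1.21-fold, TAF8 was 1.21-fold lower, and TBP, TAF2, TAF7, TAF9, TAF10 and TAF13 did not pass. Of p53 targets, 13 of 25 were higher and 4 lower (14 higher and 4 lower adjusted over the list alone), with POLH 1.46-fold, CDKN1A 1.32-fold, XPC 1.27-fold and TNFRSF10B 1.2-fold higher (camera adjusted p = 0.00368, but adjusted p = 0.0704 with an estimated correlation). Immediate early genes had 14 of 27 higher and 7 lower (14 higher and 7 lower adjusted over the list alone), with JUNB 1.65-fold, DUSP1 1.39-fold, JUN 1.27-fold and IER5 1.2-fold higher (camera adjusted p = 0.00505, but adjusted p = 0.197 with an estimated correlation). G1/S genes went both ways, 16 of 30 lower and 7 higher (7 higher and 17 lower adjusted over the list alone), with E2F1 1.35-fold lower and RRM2 1.32-fold higher (camera adjusted p = 0.0128, but adjusted p = 0.390 with an estimated correlation). Ribosome biogenesis genes had 13 of 29 lower and 3 higher (3 higher and 13 lower adjusted over the list alone), with GNL3 1.27-fold and RRS1 1.22-fold lower (camera adjusted p = 0.00634, but adjusted p = 0.197 with an estimated correlation). Neuronal genes had 10 of 22 lower and 2 higher (3 higher and 11 lower adjusted over the list alone), with STMN3 1.37-fold lower (camera adjusted p = 0.0236, but adjusted p = 0.306 with an estimated correlation). Keratin-rich epithelial markers had 5 of 8 lower and 0 higher (0 higher and 5 lower adjusted over the list alone), with CDH1 1.7-fold lower (camera adjusted p = 0.010, but adjusted p = 0.235 with an estimated correlation). Neuronal genes lost their call without ΔE8 replicate 3 (camera adjusted p = 0.0562). Doxycycline dose differed between the FL and ΔE8 groups, and TAF5 counts were 1.2-fold lower in ΔE8, without correction for its shorter transcript. The FL and ΔE8 cells also carried different transgenes, so they may differ as cell lines. The dose, the TAF5 level and the cell line cannot be separated from the missing exon.

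Full-length rescue against siNT asked how far expression still differed from cells with endogenous TAF5. DNAH17 (4.22-fold, 5.69 ± 0.492 to 24.1 ± 2.94 CPM; chromosome 17, 78423697 to 78577396), HSPB8 (3.03-fold), TAF5 (2.63-fold) and the stress phosphatase subunit PPP1R15A (2.45-fold, 40.5 ± 0.556 to 99.2 ± 4.43 CPM, edgeR adjusted p = 3.93e-16) were highest above siNT. STC1 (3.36-fold, 12.1 ± 0.751 to 3.5 ± 1.01 CPM), the adhesion gene ICAM5 (3.14-fold, 36.9 ± 2.84 to 11.7 ± 1.05 CPM, edgeR adjusted p = 6.48e-13), PCK1 (3.14-fold) and IL32 (3.06-fold) were lowest. The test called 5397 genes higher and 5211 lower (54.6%; edgeR quasi-likelihood, Benjamini-Hochberg), with 268 and 415 at least 2-fold and a median size of 0.286. Library totals only gave 5054 and 5502, and upper-quartile factors 4676 and 5864. Libraries did not overlap for 59.7% of genes, against 10% by chance. Of 28 lists, limma camera called 18 with the preset correlation and 0 with an estimated one, where adjusted p of the 18 lay between 0.077 and 0.6 and 10 lists had an unadjusted p under 0.05; fry called 25. Splicing factor genes had 25 of 32 higher and 1 lower (27 higher and 1 lower adjusted over the list alone), with HNRNPM 1.74-fold and SRSF6 1.72-fold higher (camera adjusted p = 1.12e-11, but adjusted p = 0.0902 with an estimated correlation). Heat shock genes had 12 of 16 higher and 1 lower (12 higher and 1 lower adjusted over the list alone), with DNAJA1 1.69-fold and HSPA8 1.55-fold higher (camera adjusted p = 4.29e-05, but adjusted p = 0.128 with an estimated correlation). Ribosomal protein genes stayed below siNT, 63 of 76 lower and 2 higher (2 higher and 64 lower adjusted over the list alone), median -0.12 (camera adjusted p = 1.12e-11, but adjusted p = 0.259 with an estimated correlation). Histone genes lay below siNT, 8 of 18 lower and 2 higher (2 higher and 8 lower adjusted over the list alone), with H2AC18 3.0-fold and H1-2 2.11-fold lower (camera adjusted p = 0.0178, but adjusted p = 0.128 with an estimated correlation). Their median was -0.21, and -0.33 without FL replicate 2. Extracellular matrix genes had 16 of 24 lower and 5 higher (5 higher and 16 lower adjusted over the list alone), with LAMB1 1.42-fold and COL5A1 1.62-fold lower (camera adjusted p = 0.000137, but adjusted p = 0.128 with an estimated correlation). Mitochondrially encoded genes had 11 of 13 lower and 0 higher (0 higher and 12 lower adjusted over the list alone), median -0.31 (camera adjusted p = 0.000224, but adjusted p = 0.413 with an estimated correlation). Of 3 fibroblast markers 2 were lower and 0 higher (0 higher and 2 lower adjusted over the list alone), COL1A1 1.82-fold and COL3A1 1.75-fold, median -0.80 (camera adjusted p = 0.0374, but adjusted p = 0.128 with an estimated correlation). The p53 list was not called (12 of 25 higher and 5 lower, 12 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.359).

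The other 11 lists called in FL against siNT also lost their call with an estimated correlation. TFIID subunits had 8 of 15 higher and 2 lower (8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0353, but adjusted p = 0.128 with an estimated correlation). SAGA subunits had 10 of 16 higher and 0 lower (10 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0452, but adjusted p = 0.128 with an estimated correlation). RNA polymerase II and general factor genes had 19 of 29 higher and 2 lower (19 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000401, but adjusted p = 0.128 with an estimated correlation). Mediator subunits had 21 of 32 higher and 3 lower (21 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.000119, but adjusted p = 0.0770 with an estimated correlation). G1/S genes had 24 of 30 higher and 3 lower (24 higher and 3 lower adjusted over the list alone, camera adjusted p = 7.93e-08, but adjusted p = 0.128 with an estimated correlation). G2/M genes had 20 of 27 higher and 4 lower (20 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.000401, but adjusted p = 0.259 with an estimated correlation). Ribosome biogenesis genes had 22 of 29 higher and 2 lower (22 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.25e-06, but adjusted p = 0.0770 with an estimated correlation). Unfolded protein response genes had 14 of 18 higher and 1 lower (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.19e-05, but adjusted p = 0.149 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had 27 of 48 higher and 6 lower (28 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00146, but adjusted p = 0.480 with an estimated correlation). ATF4 pathway genes had 17 of 29 lower and 8 higher (9 higher and 18 lower adjusted over the list alone, camera adjusted p = 0.0441, but adjusted p = 0.60 with an estimated correlation). Glycolysis and hypoxia genes had 18 of 29 lower and 7 higher (7 higher and 18 lower adjusted over the list alone, camera adjusted p = 0.00491, but adjusted p = 0.480 with an estimated correlation). SAGA lost its call without siNT replicate 1 (camera adjusted p = 0.0514), siNT replicate 2 (0.0536) or FL replicate 2 (0.101), and the ATF4 list without siNT replicate 1 (0.0608) or FL replicate 3 (0.0698).

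ΔE8 against siNT gave the most calls of the 6 comparisons. ZNF425 (4.44-fold, 3.24 ± 0.215 to 14.4 ± 0.594 CPM, edgeR adjusted p = 6.95e-15), DHRS2 (3.48-fold), DNAH17 (3.37-fold) and H4C8 (3.15-fold) rose most. BST2 (6.03-fold, 8.21 ± 0.484 to 1.35 ± 0.113 CPM, edgeR adjusted p = 3.28e-13; chromosome 19, 17402939 to 17405630), IL32 (3.9-fold), CALML4 (3.64-fold) and PCDH19 (3.63-fold) fell most. ZNF425, DHRS2, H4C8, BST2, CALML4 and PCDH19 were also among the most changed genes in siTAF5. POLR2A reached 926 ± 24.9 CPM, 2.7-fold its siNT level, with SE 0.024 on the log2 scale (edgeR adjusted p = 2.85e-19), and the autophagy receptor SQSTM1 313 ± 14.5 CPM, 2.19-fold. The test called 5987 genes higher and 6104 lower (62.2%; edgeR quasi-likelihood, Benjamini-Hochberg), with 518 and 792 at least 2-fold and a median size of 0.361. Library totals only gave 6221 and 5920, and upper-quartile factors 5309 and 6862. Libraries did not overlap for 65.7% of genes, against 10% by chance. Of 28 lists, limma camera called 18 with the preset correlation and 0 with an estimated one, where adjusted p of the 18 lay between 0.0654 and 0.528 and 6 lists had an unadjusted p under 0.05; fry called 27. Ribosomal protein genes had 69 of 76 lower and 2 higher (2 higher and 69 lower adjusted over the list alone), median -0.33 (camera adjusted p = 8.40e-22, but adjusted p = 0.230 with an estimated correlation). ATF4 pathway genes had 24 of 29 lower and 3 higher (3 higher and 24 lower adjusted over the list alone), with ASNS 1.73-fold lower and SLC3A2 1.6-fold higher (camera adjusted p = 3.18e-06, but adjusted p = 0.284 with an estimated correlation). Histone genes had 12 of 18 higher and 0 lower (12 higher and 0 lower adjusted over the list alone), median 0.76 (camera adjusted p = 0.00117, but adjusted p = 0.0654 with an estimated correlation). Mediator subunits had 23 of 32 higher and 3 lower (24 higher and 3 lower adjusted over the list alone), with MED29 1.76-fold higher (camera adjusted p = 0.000148, but adjusted p = 0.0654 with an estimated correlation). TFIID subunits had 11 of 15 higher and 2 lower (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00190, but adjusted p = 0.0654 with an estimated correlation).

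The other 13 lists called in ΔE8 against siNT lost their call in the same way. The p53 targets had 16 of 25 higher and 4 lower (16 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00574, but adjusted p = 0.0654 with an estimated correlation). RNA polymerase II and general factor genes had 18 of 29 higher and 2 lower (19 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00136, but adjusted p = 0.230 with an estimated correlation). G1/S genes had 20 of 30 higher and 7 lower (20 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00632, but adjusted p = 0.343 with an estimated correlation). Ribosome biogenesis genes had 17 of 29 higher and 5 lower (19 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.00646, but adjusted p = 0.242 with an estimated correlation). Unfolded protein response genes had 12 of 18 higher and 0 lower (12 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.00136, but adjusted p = 0.284 with an estimated correlation). Heat shock genes had 11 of 16 higher and 4 lower (11 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0136, but adjusted p = 0.351 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had 29 of 48 higher and 8 lower (29 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.00468, but adjusted p = 0.476 with an estimated correlation). Splicing factor genes had 24 of 32 higher and 8 lower (24 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.00232, but adjusted p = 0.324 with an estimated correlation). Lysosome and autophagy genes had 14 of 24 higher and 9 lower (14 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0334, but adjusted p = 0.284 with an estimated correlation). Mitochondrially encoded genes had 11 of 13 lower and 0 higher (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.00136, but adjusted p = 0.441 with an estimated correlation). Keratin-rich epithelial markers had 5 of 8 lower and 1 higher (1 higher and 5 lower adjusted over the list alone), with CDH1 3.16-fold lower (camera adjusted p = 0.030, but adjusted p = 0.324 with an estimated correlation). Extracellular matrix genes had 15 of 24 lower and 5 higher (5 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.00697, but adjusted p = 0.284 with an estimated correlation). Glycolysis and hypoxia genes had 17 of 29 lower and 6 higher (7 higher and 17 lower adjusted over the list alone, camera adjusted p = 0.0295, but adjusted p = 0.528 with an estimated correlation).

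The siNT libraries were shared by 3 comparisons. Genes called in both siTAF5 and FL against siNT numbered 2804 higher and 2846 lower, where independent lists would share 1334 and 1301. The correlation across genes was 0.524 (0.475 simulated) and the covariance 0.0844 (0.0161 simulated). For siTAF5 and ΔE8 against siNT they numbered 3977 and 4034 (1480 and 1523 for independent lists), with a correlation of 0.766 (0.482 simulated) and a covariance of 0.152 (0.0161 simulated). For FL and ΔE8 against siNT they numbered 4245 and 4210 (1664 and 1638), with a correlation of 0.78 (0.475 simulated) and a covariance of 0.17 (0.0163 simulated). Genes are not independent replicates. The 3 controls are too few to give each comparison 2 of its own, so part of each excess in counts and correlation may come from the shared controls, while the simulated covariance holds that part.

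Whether the isoform difference follows the depletion response was asked without any shared library, by taking the genes called in siTAF5 against siNT and testing them in ΔE8 against FL. Of 4802 genes higher in siTAF5, 2553 were higher in ΔE8 than in FL and 82 lower, where independent lists would give 830 and 944. Their median log2 difference was 0.15, and 87.3% were above 0 (camera p = 5.17e-53, and p = 2.36e-06 with an estimated correlation). Of 4847 genes lower in siTAF5, with TAF5 left out, 67 were higher in ΔE8 than in FL and 2886 lower (838 and 953 for independent lists), with a median of -0.17 and 90.1% below 0 (camera p = 1.39e-55, and p = 2.51e-05 with an estimated correlation). Among genes changed at least 2-fold by siTAF5, 134 of 323 higher genes were higher in ΔE8 and 0 lower (median 0.62), and 68 of 196 lower genes were lower and 1 higher (median -0.57). Across genes the correlation between the 2 comparisons was 0.543 against 0.000737 in simulations, and the covariance 0.0674 against 2.38e-05.

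The share of the siTAF5 response that was left in each rescued group was estimated in held-out libraries. In FL 61.7% ± 1.39 of the summed log2 response to siTAF5 was left, and in ΔE8 124% ± 1.99 (mean ± SD over 3 folds, whose gene choices overlap). Of 519 genes changed at least 2-fold by siTAF5, 255 were still called the same way against siNT in FL and 418 in ΔE8, 250 and 100 were not called, and 14 and 1 were called the opposite way. The siTAF5 and siNT libraries enter both the choice of these 519 genes and the counts, so the counts describe these libraries. The labels do not state in which inducible line the siNT and siTAF5 cells were grown, so differences of either rescued group from them may include a difference between lines.

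**Figure D4:**
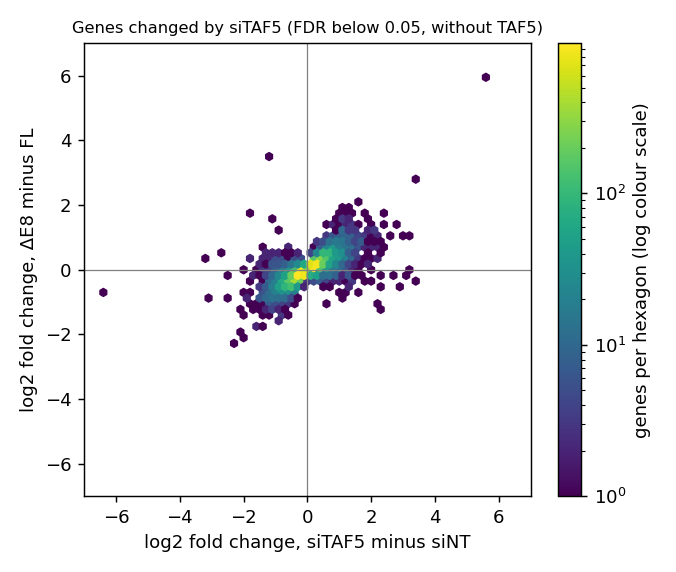
Log2 fold change in siTAF5 minus siNT (x axis) against that in ΔE8 minus FL (y axis) for the genes called in siTAF5 against siNT, TAF5 left out, with the colour giving genes per hexagon on a log scale. The comparisons share no library, and the correlation across all tested genes was 0.543.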

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

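Tests without the 3 libraries under 45 M counts (FL replicates 2 and 3, ΔE8 replicate 3), thinned to the smallest library, without histone and ribosomal protein genes, and of the lists with each library left out were chosen after the results were seen. The number of genes called stayed within 1.5 times in each comparison under the DESeq2 Wald test, which gave 8609, 8478, 7034, 6311, 9506 and 11060 genes for siTAF5 against siNT, FL against siTAF5, ΔE8 against siTAF5, ΔE8 against FL, FL against siNT and ΔE8 against siNT, where edgeR gave 9650, 9477, 7884, 7178, 10608 and 12091. The same held for the other scalings and filters and for the 6 libraries alone. Leaving out each library in turn gave 8655 to 9019, 8613 to 8846, 6884 to 7195, 6127 to 6543, 9705 to 9970 and 11494 to 11621 genes, in the same order. A minimum of 2-fold left 520, 537, 298, 230, 683 and 1310 genes, by its construction. Without the 3 smaller libraries, ΔE8 against FL gave 4767 genes; this leaves FL with 1 library, which is assumed to vary like the other groups, and fewer libraries are part of that drop. Thinning every library to the smallest gave 9165, 9023, 7538, 6769, 10089 and 11534 genes, fewer in each comparison than at full depth, so depth limits the number of calls. The balance of calls moved with the scaling. Genes higher and lower were 4802 and 4848, 4745 and 4732, 3891 and 3993, 3359 and 3819, 5397 and 5211, and 5987 and 6104 in the same order. With library totals only they were 5662 and 4140, 3748 and 5788, 3321 and 4546, 4072 and 3184, 5054 and 5502, and 6221 and 5920. Upper-quartile factors gave 4459 and 5254, 4392 and 5095, 3201 and 4687, 3168 and 4130, 4676 and 5864, and 5309 and 6862. Relative log expression factors gave 4726 and 4927, 4756 and 4724, 4018 and 3892, 3469 and 3713, 5334 and 5267, and 6016 and 6085. In each comparison the larger side turned with at least 1 of these, so which side is larger is left open in all 6. With library totals only, the median log2 change over all genes was at most 0.0532 in size.

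The lists depended most on how correlation between genes was handled. With an estimated correlation, camera called 2, 4, 0, 1, 0 and 0 lists in the same order of comparisons, where the preset correlation called 9, 13, 15, 11, 18 and 18; in the 3 comparisons with 0 lists, 10, 10 and 6 had an unadjusted p under 0.05, and fry called 19, 25 and 27. Fry, which does not compare a list with other genes, called 19 lists in siTAF5 against siNT, 22 in FL against siTAF5 and 23 in ΔE8 against FL. The difference comes from the assumed correlation and the question each test asks, and no other cause was tested. Leaving out each library in turn gave 8 to 11, 12 to 14, 14 to 16, 10 to 13, 16 to 19 and 18 lists. Library totals ended the calls of the SAGA and apoptosis lists in FL against siTAF5 (adjusted p = 0.118 and 0.0887) and of SAGA in FL against siNT (0.0649). The siTAF5-response lists kept their direction and call in ΔE8 against FL, with medians of 0.145 to 0.159 and -0.178 to -0.159 over the libraries left out in turn, and 0.149 and -0.168 without histone and ribosomal protein genes. The share of the siTAF5 response left was 53.4% in FL and 114% in ΔE8 over genes changed at least 2-fold, and 67.7% and 132% as a median over genes, against 61.7% and 124%; the cause was not tested. Single genes were followed only where the naming rule chose them, so other called genes were not checked one by one. No named gene or list that was called changed direction, but the larger side of the counts of calls did, as given above. Some uncalled values near 0 changed sign, such as TBP in FL against siTAF5 (-0.02 with library totals only, adjusted p = 0.697). Among tests of the named genes and lists, 8866 stayed on the same side of the threshold, 113 newly passed and 141 no longer did. The named genes that lost their call were TFIID subunits with small changes, and only TFIID subunits were followed whatever the size of their change. TAF2 in siTAF5 against siNT lost its call without any 1 of the 6 libraries (adjusted p = 0.0664 to 0.238). TAF11 in ΔE8 against FL lost its call without FL replicate 1 (adjusted p = 0.131), FL replicate 2 (0.0876), ΔE8 replicate 1 (0.0645) or ΔE8 replicate 3 (0.0893).

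Replicate numbers were also tried as a block. This gave 9787, 9602, 8092, 7409, 10687 and 12215 genes in the same order and 10, 13, 15, 11, 19 and 18 lists. TAF2 in siTAF5 against siNT lost its call (adjusted p = 0.051). Libraries with the same number in different groups had a median residual correlation of 0.0806 (-0.177 to 0.304 over 18 pairs). With only 8 of these above 0.1, the numbers were not taken to pair the samples. Even so, 9 of the 12 libraries had their highest mean correlation, over the other groups, with libraries of their own number.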

Other observations

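The tests of S phase, of one insertion site as the source of most genes, of a difference of line or dose, and of families and RNAs without a tail with libraries left out were chosen after the results were seen, as were 16 gene families defined by symbol or biotype and every gene named here. Proteasome genes were higher in both rescued groups than in siTAF5. In FL against siTAF5 33 of 43 were higher and 0 lower (median 0.26, camera adjusted p = 5.38e-13, but adjusted p = 0.126 with an estimated correlation). In ΔE8 against siTAF5 these were 33 and 0 (median 0.20, camera adjusted p = 4.39e-16, but 0.229). PSMC4, a subunit of the proteasome base, stood at 196 ± 1.74 CPM in siNT, 224 ± 4.46 in siTAF5, 293 ± 6.67 in FL and 284 ± 2.43 in ΔE8 (n = 3). Chaperonin genes followed with 10 of 13 higher and 1 lower in FL and 10 and 0 in ΔE8 against siTAF5. Of 84 mitochondrial ribosomal protein genes, 48 were higher and 10 lower in FL, and 48 and 2 in ΔE8. Neither family kept its call: chaperonin genes had camera adjusted p = 6.62e-05 in FL and 7.89e-07 in ΔE8, but adjusted p = 0.178 and 0.229 with an estimated correlation. For mitochondrial ribosomal protein genes these were camera adjusted p = 1.10e-05 and 2.90e-10, but 0.178 and 0.229. The chaperonin gene CCT2 rose from 367 ± 6.11 CPM in siTAF5 to 482 ± 10.9 in FL and 448 ± 10.9 in ΔE8. Most called members of these families rose in both rescued groups, but as families their rise depended on the preset correlation. In ΔE8 against FL the proteasome family was not called (camera adjusted p = 0.205). Proteasome, chaperonin and mitochondrial ribosomal protein genes were not called in siTAF5 against siNT (camera adjusted p = 0.0988, 0.761 and 0.181). Medians over siNT, in this order, were 0.053, -0.0134 and 0.058 in siTAF5, 0.286, 0.225 and 0.128 in FL, and 0.248, 0.209 and 0.158 in ΔE8. The rises were thus not a return to siNT. A difference of cell line or doxycycline dose cannot be told apart from the transgene here.

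In siTAF5 against siNT, 176 of 622 antisense genes were higher and 43 lower (median 0.20, camera adjusted p = 0.0130, and 0.0355 with an estimated correlation), and in FL against siTAF5 185 were lower and 43 higher (median -0.22, camera adjusted p = 0.00353, and 0.0311). In ΔE8 against FL 110 were higher and 36 lower (median 0.12, camera adjusted p = 0.0417, but adjusted p = 0.0917 with an estimated correlation). That call was also lost without FL replicate 1, 2 or 3 (camera adjusted p = 0.0986, 0.0615 and 0.0512) and without ΔE8 replicate 2 or 3 (0.110 and 0.0877). The family was not called in ΔE8 against siTAF5 (camera adjusted p = 0.249), FL against siNT (0.998) or ΔE8 against siNT (0.313). Their counts depend on the strand setting, which is not given in the sources used here. Of 14 host genes of small nucleolar RNAs, 12 fell and 0 rose in siTAF5 (median -0.47, camera adjusted p = 1.51e-08, and adjusted p = 0.0170 with an estimated correlation), and in ΔE8 against FL 9 were lower and 1 higher (median -0.26, camera adjusted p = 8.08e-06, and 0.0268); these were adjusted over 2 lists. The wider family of 25 SNHG genes had 16 lower and 2 higher in siTAF5 (median -0.30, camera adjusted p = 6.74e-05, but 0.110 with an estimated correlation). In ΔE8 against FL it had 13 lower and 2 higher (median -0.25, camera adjusted p = 5.67e-05, but 0.124), so a change of the whole class is left open. SNHG8 stood at 25.4 ± 1.2 CPM in siNT, 16.8 ± 0.811 in siTAF5, 23.6 ± 0.939 in FL and 17.5 ± 0.408 in ΔE8 (n = 3).

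Histone transcripts were higher in ΔE8 than in FL, and 3 sources of such a difference were tested. RNAs without a poly(A) tail, which would rise if polyA selection had been weaker, had a summed log2 ratio of -0.0606 (SE 0.278), below the 0.3 set as the bound. This hung on FL replicate 2, with 87.24 CPM of these RNAs against 48.4 and 52.38: without it the ratio was 0.204 (SE 0.0972), no longer below 0.3 by more than its SE. It stayed below 1.5-fold, the rise that carry-over was expected to give, by more than its SE without any 1 of the 6 libraries (-0.221 to 0.204), which argues against carry-over as the whole source. Reads shared between near-identical copies would leave the sum over the 59 genes alike, but the sum differed by 1.25 on the log2 scale (SE 0.0238). More cells in S phase were expected to raise the G1/S list too, although this list does not measure the share of cells in S phase. That list had a median of -0.0748 with 7 members higher and 16 lower. In FL against siTAF5, 24 of 30 of its genes were higher and 1 lower (median 0.213), while the histone sum fell by 1.67 on the log2 scale. The list median and the histone sum thus moved in opposite directions in both comparisons. This test cannot decide on S phase, since list members go both ways in ΔE8 against FL. The list calls in ΔE8 against FL and in FL against siTAF5 were also lost with an estimated correlation (camera adjusted p = 0.39 and 0.0869). A change in how often histone transcripts carry poly(A) tails may contribute and was not tested.

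Most ribosomal protein transcripts were lower in siTAF5 than in siNT (68 of 76) and in ΔE8 than in FL (66), and this was weighed against length or expression bias. The list lost its call with an estimated correlation (camera adjusted p = 1.74e-25 and 4.47e-27, but 0.205 and 0.182). The 159 genes matched on annotated length and expression had medians of -0.0739 and -0.0502, against -0.249 and -0.2 for the ribosomal protein genes. This argues against expression bias as the whole source. Lengths of the transcripts counted were not known, so length bias is left open. Of 23 translation factor and other 5' TOP genes, 23 were lower in siTAF5 (median -0.24) and 18 in ΔE8 than in FL (median -0.2), so the change was shared with that class. FAU in this list itself encodes a ribosomal protein. A change of 5' TOP transcripts is therefore a candidate explanation, and pseudogene reads remain untested.

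In both rescued groups 83 genes were at least 1.5-fold higher than in both groups without a transgene, and 183 were lower. In the test fixed first, 14.5% of the 83 had another of them within 500 kb, above 13.3%, the 95th percentile of 1000 random sets. The close pairs lay on chromosomes 1, 10, 16, 17, 19 and 21. This argues against one insertion site as their common source. Reads shared within pairs, such as RFPL4A and RFPL4AL1, were not tested. A later test asked whether one site held most of the 83. They lay on 22 chromosomes, and at most 2 (2.41%) shared a 500-kb stretch. Genes picked over the whole genome could hardly lie that close, so local effects of one site stay open. A difference of cell line or doxycycline dose cannot be told apart from the transgene for these 83 genes, since uninduced lines were not analysed here. Some of them, such as PIK3CG (0.0272 ± 0.0339 CPM in siNT and 0.601 ± 0.102 in FL), had few counts.

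Other splits of the 6 libraries of each comparison into groups of 3 were fitted as well. In each comparison 1 of 10 splits, the real one, gave as many calls as observed, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 9650 and 1 for siTAF5 against siNT, 9477 and 0 for FL against siTAF5, 7884 and 1 for ΔE8 against siTAF5, 7178 and 0 for ΔE8 against FL, 10608 and 0 for FL against siNT, and 12091 and 0 for ΔE8 against siNT.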
